A study of Homo sapiens with 7 samples.

How the data were processed

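Native chromatin of SK-mel147 melanoma cells and of melanocytes was digested with micrococcal nuclease, and mononucleosomes were precipitated with an H2A.Z antibody or GFP-binding beads, per the labels' protocols. Libraries were sequenced as 100-bp single-end Illumina reads. The submitters' processing notes name FastQC, Bowtie with no version, MACS2 2.1.0 and 2.0.10, bedtools 2.17.0 and deepTools 1.5.7, without saying which step each served. They name hg19 as the genome build, as do the peak names in the files. Peaks were called in broad mode with MACS at a threshold of 0.005, per the peak names, with a separate list for each sample. The control library of each call, read filters and duplicate handling are not given in the sources used here. A control that differed between the antibody and bead libraries would change which peaks were called.

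Each deposited list holds a chromosome, start, end, name and score per peak. The authors' score is a whole number that starts at 23 in all 3 lists, which is the value of 10 times the −log10 of the threshold of 0.005 (23.01) rounded down. It is therefore read as 10 times a −log10 value, and whether that is a p-value or a q-value is not given. Scores were used to rank peaks within a list and never compared between lists. Peaks of equal score were ranked by width, the wider first, and then by position. Starts were converted to positions counted from 1. Of the 88897 endogenous peaks 1 lay outside chromosomes 1 to 22 and X and was left out, and none was left out of the tagged lists. No peak was shorter than 300 bp, and no pair of peaks in one list lay closer than 1201 bp. The files hold no read counts, so depth is unknown, and a library read more deeply can yield more and wider peaks.

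Samples were grouped by their titles, with 1 library per group. No p-value was computed. Lists were compared in 6 directions by the percentage of peaks overlapping the other list by at least 1 bp, with exact (Clopper-Pearson) 95% intervals. The chance level came from 100 rotations of the list along each chromosome by at least 5% of its length. A second chance level, chosen after the data were examined, moved the list by 20 to 100 kb. Both were also applied to the peaks of 5 kb or more alone. Density on X, wide peaks, bins of 5 Mb (ratios only where the bin held at least 25 peaks), chromosomes and groups of 10% of the peaks by score were also examined after the lists had been seen. To compare chromosomes at like peaks, each peak was given the overlap expected from autosomal peaks of other chromosomes in the same class of score and width. A further version added the number of endogenous peaks in a window of 1 Mb around the peak, in 10 classes or as the number itself. Both forms used coarser classes of width, and the second pooled the highest numbers. In the second form 99.1% of X peaks had a match, and the others were left out. Peaks per Mb were taken over the span of each chromosome that holds peaks. Of the alternatives to the overlap rule and the authors' threshold, the overlap of 50%, the better-scored 50% of each list, equal-length lists and the merge at 1 kb were fixed before the data were examined. Others were added afterwards, and the effect of all is given in the closing section.

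The rule for named items was fixed before the data were examined. It takes the 3 best-scored peaks of each list and the 3 best-scored peaks found in one tagged list alone, by position. The widest peaks and the bins were named after their values were seen. The planned shares of peaks at promoters, counts of genes with a promoter peak and gene lists needed a gene annotation of hg19, which was not used here, and these were not run.

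Calculations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and plots matplotlib 3.10.9. The overlap counter was tested on simulated lists of 20000 peaks, where its largest error was 0.0 percentage points, and on the real lists it differed by 0 peaks from bedtools 2.31.1 in 12 counts. The matching by score and width was tested on the 88896 endogenous peaks with simulated overlaps. It gave a residual of 0.52 percentage points on X with no effect put in, and −19.98 with the overlap on X lowered by 20 points. The simulated overlaps depended only on the same classes of score and width, so this checks the arithmetic of the matching. It cannot show that matching removes the effects of score and width in the real lists. The versions with local peak density were not tested in this way.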

Results

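Mononucleosomes carrying the histone variant H2A.Z were mapped in SK-mel147 cells, a human melanoma line with a mutant NRAS gene. H2A.Z replaces canonical H2A in a share of nucleosomes, typically at promoters and enhancers, and exists as the isoforms H2A.Z.1 and H2A.Z.2, which are products of separate genes and differ at few residues. Chromatin was digested with micrococcal nuclease without crosslinking and precipitated either with an H2A.Z antibody from the unmodified line or with GFP-binding beads from lines that stably expressed either isoform fused to eGFP (eGFP-H2A.Z.1, eGFP-H2A.Z.2) after lentiviral transduction. The antibody list is called endogenous H2A.Z below, and it does not separate the isoforms. The series holds 7 libraries, 1 per group, and 3 of them are compared here through their peak lists. The input and the eGFP-H2A control of the same line, and the H2A.Z and input libraries of melanocytes, were not analysed here. There were no replicates, so differences between lists have no test against replicate error, and the read depth of each library is unknown. Confidence intervals are exact (Clopper-Pearson) 95% intervals that cover counting error only. Positions are on hg19, counted from 1. No gene annotation of that build was used here, so peaks are named by position.

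The endogenous list held 88896 peaks on chromosomes 1 to 22 and X, covering 102.2 Mb. The eGFP-H2A.Z.1 list held 110067 peaks over 156.0 Mb and the eGFP-H2A.Z.2 list 95028 peaks over 139.9 Mb. Median peak width was 881 bp for endogenous H2A.Z, 1010 bp for eGFP-H2A.Z.1 and 1027 bp for eGFP-H2A.Z.2. The best-scored endogenous peak lay on chromosome X from 77359130 to 77360027, with a score of 824 against 363 for the next, on chromosome 1 from 89529449 to 89531637. What lies under the peak on X was not determined. It was called in the unmodified line and in neither of the transduced lines. The next endogenous peak, with a score of 333, lay on chromosome 1 from 70874534 to 70877763. In the eGFP-H2A.Z.1 list the best peaks were on chromosome 9 from 110462702 to 110463849, on chromosome 2 from 210653744 to 210656049 and on chromosome 2 from 151259203 to 151261022, with scores of 225, 215 and 198. In the eGFP-H2A.Z.2 list they were on chromosome 1 from 89530090 to 89531739, on chromosome 2 from 210653757 to 210655690 and on chromosome 9 from 110492524 to 110496923, with scores of 202, 175 and 171. The best eGFP-H2A.Z.2 peak, on chromosome 1, overlapped the second-ranked endogenous peak, and the second-ranked peaks of both tagged lists lay at the same place on chromosome 2. Scores are the authors' and rank peaks within a list only.

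The first comparison asks whether the isoforms occupy the same sites. Most sites were shared: 67.4% of eGFP-H2A.Z.1 peaks (95% interval 67.1 to 67.7) overlapped an eGFP-H2A.Z.2 peak by at least 1 bp, and 77.5% of eGFP-H2A.Z.2 peaks (77.3 to 77.8) overlapped an eGFP-H2A.Z.1 peak. When the list was rotated along each chromosome, the mean over 100 rotations was 9.76% and 11.2%. When it was moved by only 20 to 100 kb, which keeps the regional density of peaks, the means were 20.8% and 23.8%. The lists had 90.2 Mb in common, 43.9% of the sequence covered by either. The share rose with the score. Of the lowest-scored 10% of eGFP-H2A.Z.1 peaks, 32.1% had an eGFP-H2A.Z.2 peak, against 96.4% of the best-scored 10%. The corresponding shares of eGFP-H2A.Z.2 peaks were 46.2% and 97.8%. Median width also differed between these groups, 701 and 1348 bp for eGFP-H2A.Z.1 and 695 and 1346 bp for eGFP-H2A.Z.2. Wider peaks meet another list more easily, so score and width were not told apart here. With an overlap of at least 50% of both peaks required, the shares of all peaks were 40.3% and 46.7%.

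**Figure D1:**
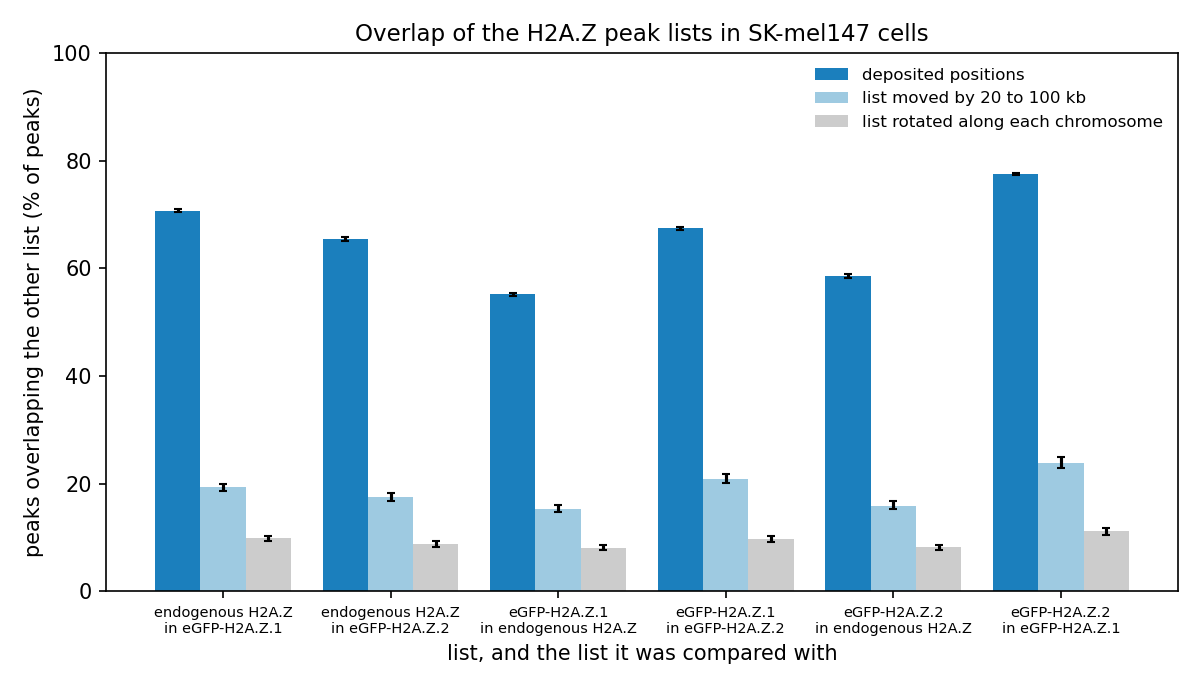
Bars give the percentage of peaks in each list that overlap the other list by at least 1 bp, at the deposited positions and with one list moved by 20 to 100 kb or rotated along each chromosome. Error bars are exact 95% intervals for the deposited positions and the span of the shifted lists for the others; the observed shares run from 55.2% to 77.5% and every shifted mean is at or below 23.8%.

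Peaks found in one isoform's list alone were narrower and lower in score than shared ones. They numbered 35873 for eGFP-H2A.Z.1 and 21362 for eGFP-H2A.Z.2. Median width was 661 bp for eGFP-H2A.Z.1 peaks without and 1243 bp for those with an eGFP-H2A.Z.2 peak, and 654 against 1177 bp in the reverse direction. Few were strong, 392 of the 11006 peaks in the best-scored 10% of eGFP-H2A.Z.1 and 211 of 9502 for eGFP-H2A.Z.2. The best-scored peak of eGFP-H2A.Z.1 alone was on chromosome 1 from 240739372 to 240740413, with a score of 112, and lay 1070 bp from the nearest eGFP-H2A.Z.2 peak. The next were on chromosome 1 from 111942670 to 111944099 (score 111), 53635 bp from an eGFP-H2A.Z.2 peak, and on chromosome 3 from 189614298 to 189614743 (score 101), 1750 bp away. The best of eGFP-H2A.Z.2 alone was on chromosome 12 from 50469224 to 50469571, with a score of 104 and an eGFP-H2A.Z.1 peak 4339 bp away. It was followed by peaks on chromosome 2 from 98232208 to 98232598 (score 88) and on chromosome 17 from 41745207 to 41745622 (score 86).

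The second comparison sets each tagged isoform against H2A.Z in the unmodified line. Of the endogenous peaks, 70.7% (70.4 to 71.0) overlapped an eGFP-H2A.Z.1 peak and 65.4% (65.1 to 65.8) an eGFP-H2A.Z.2 peak, against 9.94% and 8.81% with rotated lists and 19.3% and 17.5% with lists moved by 20 to 100 kb. In the other direction, 55.2% of eGFP-H2A.Z.1 peaks (54.9 to 55.4) and 58.6% of eGFP-H2A.Z.2 peaks (58.3 to 58.9) overlapped an endogenous peak. The eGFP-H2A.Z.1 list is the longer of the tagged lists, and a longer list is met more often: with all lists cut to the same length, 64.7% of endogenous peaks met eGFP-H2A.Z.1 and 63.9% met eGFP-H2A.Z.2. Endogenous peaks with both tagged isoforms numbered 52243 (58.8%). A further 10578 (11.9%) overlapped eGFP-H2A.Z.1 alone, 5929 (6.67%) eGFP-H2A.Z.2 alone and 20146 (22.7%) neither. Tagged peaks common to both isoforms had an endogenous peak in 68.3% of cases counted on the eGFP-H2A.Z.1 list and 68.1% on the eGFP-H2A.Z.2 list. For peaks of one isoform alone the shares were 27.9% and 25.7%. The groups were not matched on width or score, and peaks of one isoform alone were narrower and lower in score. In the best-scored 10% of endogenous peaks, 94.7% had an eGFP-H2A.Z.1 peak and 90.9% an eGFP-H2A.Z.2 peak, against 47.2% and 40.8% in the lowest-scored 10%. Median widths of these groups were 1279 and 713 bp, so score and width were not told apart. With an overlap of at least 50% of both peaks, 37.0% of endogenous peaks were met by eGFP-H2A.Z.1 and 33.0% by eGFP-H2A.Z.2, and 29.9% and 30.9% of the tagged peaks by endogenous H2A.Z.

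**Figure D2:**
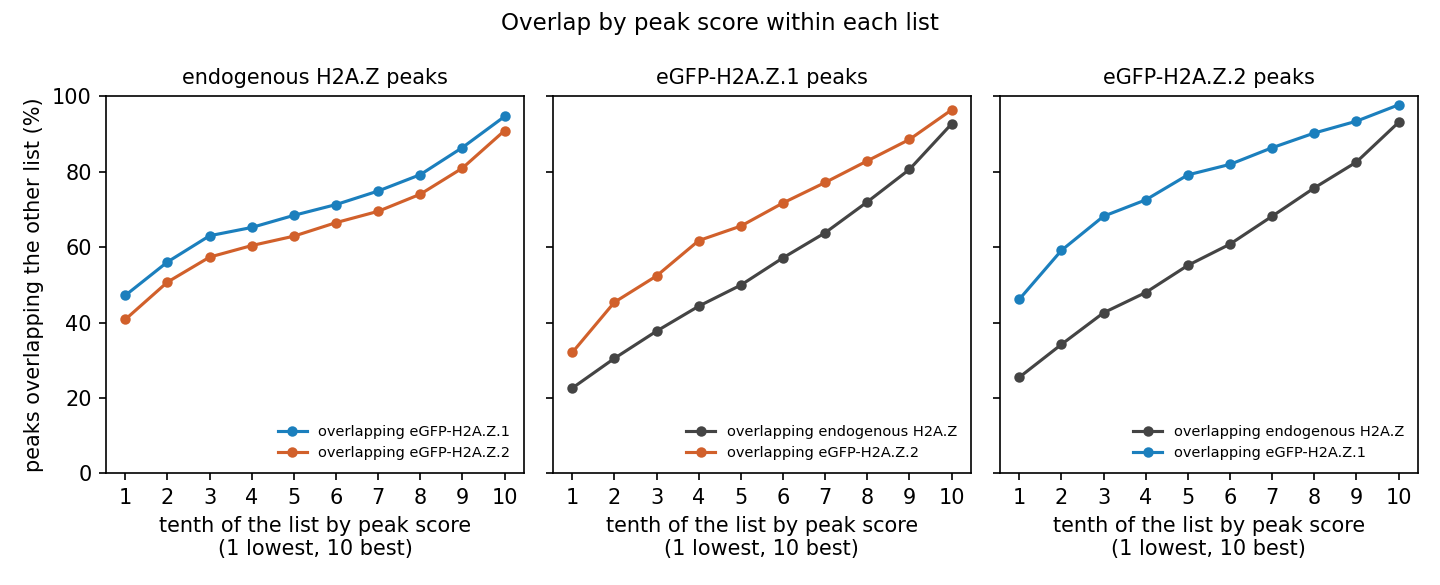
Each panel takes the peaks of one list in 10 groups of rising score (horizontal axis) and plots the percentage that overlap each of the other lists by at least 1 bp. The eGFP-H2A.Z.1 line toward eGFP-H2A.Z.2 runs from 32.1% to 96.4%, and that of endogenous H2A.Z toward eGFP-H2A.Z.1 from 47.2% to 94.7%.

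Wide peaks were more frequent in the tagged lists. Peaks of 5 kb or more numbered 620 for endogenous H2A.Z (0.697% of its peaks), 2924 for eGFP-H2A.Z.1 (2.66%) and 3000 for eGFP-H2A.Z.2 (3.16%), and held 3.79%, 13.0% and 15.6% of the covered sequence. The widest peaks of both tagged lists, eGFP-H2A.Z.1 first, marked the same place on chromosome 1, from 59586758 to 59610785 (24.0 kb) and from 59586682 to 59623136 (36.5 kb). The widest endogenous peak, on chromosome 11 from 89337376 to 89353703 (16.3 kb), lay within the second-widest eGFP-H2A.Z.2 peak, from 89320298 to 89354137 (33.8 kb). Nearly all wide peaks had a counterpart of some width: 99.6% of wide eGFP-H2A.Z.1 peaks met an eGFP-H2A.Z.2 peak and 99.9% of wide eGFP-H2A.Z.2 peaks an eGFP-H2A.Z.1 peak. Wide intervals meet another list often by chance: moved by 20 to 100 kb, the same wide peaks gave means of 60.7% and 66.2%, and rotated along the chromosome 23.0% and 26.4%. Endogenous peaks were present in 95.8% of the wide eGFP-H2A.Z.1 and 96.3% of the wide eGFP-H2A.Z.2 peaks, against 50.8% and 52.9% when these were moved by 20 to 100 kb. Fewer met a peak that was itself 5 kb or more. Between the isoforms this was 51.5% of wide eGFP-H2A.Z.1 and 49.8% of wide eGFP-H2A.Z.2 peaks. Toward wide endogenous peaks it was 12.6% and 11.8%. Of the wide endogenous peaks, 59.2% met a wide eGFP-H2A.Z.1 and 57.3% a wide eGFP-H2A.Z.2 peak. No shifted level was computed for wide partners. In 50.2% of the wide eGFP-H2A.Z.1 peaks and 53.7% of the wide eGFP-H2A.Z.2 peaks, 2 or more separate endogenous peaks lay under the single tagged peak, against 16.7% and 18.4% when moved in the same way. Between the tagged lists, 42.7% of wide eGFP-H2A.Z.1 peaks held 2 or more eGFP-H2A.Z.2 peaks, against 26.2% when moved, and the reverse was 49.9% against 31.4%. Wide endogenous peaks held 2 or more eGFP-H2A.Z.1 peaks in 30.8% of cases, against 24.0% when moved (20.2 to 30.2 over the shifts), and 2 or more eGFP-H2A.Z.2 peaks in 28.7% against 21.6% (17.6 to 26.1). All these moved values also count wide peaks that met no peak. Moved wide endogenous peaks met an eGFP-H2A.Z.1 peak in 59.2% and an eGFP-H2A.Z.2 peak in 55.9% of cases, against 98.7% and 99.2% at the deposited positions. A higher share with 2 or more peaks can thus come from meeting any peak more often, and does not by itself show splitting beyond chance. The width of 5 kb was chosen after the data were examined.

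Regions dense in H2A.Z peaks were common to the lists. Across 598 bins of 5 Mb, peak numbers of the tagged isoforms had a Spearman rho of 0.993, and those of endogenous H2A.Z had 0.973 with eGFP-H2A.Z.1 and 0.965 with eGFP-H2A.Z.2. These are correlations across bins, which are not replicates. All lists come from one parental line and its input was not analysed here, so regional copy number shared by the lists was not told apart from H2A.Z content. The densest bins lay on chromosome 1, from 195 to 200 Mb with 525 endogenous, 653 eGFP-H2A.Z.1 and 580 eGFP-H2A.Z.2 peaks, and from 190 to 195 Mb with 496, 691 and 633. Next came chromosome 5 from 160 to 165 Mb (454, 605 and 571) in the tagged lists and chromosome 16 from 60 to 65 Mb (473, 541 and 518) in the endogenous list. Over the 572 bins with at least 25 endogenous peaks, the median was 0.87 endogenous peaks per tagged peak (mean of the tagged lists), with 90% of bins between 0.699 and 1.96. This filter keeps bins with few tagged peaks but drops bins with few endogenous peaks, so it favours high ratios. Chromosome 11 from 115 to 120 Mb held 28 endogenous but 3 eGFP-H2A.Z.1 and 2 eGFP-H2A.Z.2 peaks, chromosome X from 50 to 55 Mb held 31 against 4 and 5, and chromosome 16 from 0 to 5 Mb held 79 against 26 and 18. The lowest ratio was on chromosome 14 from 95 to 100 Mb, with 232 and 216 peaks against 131 endogenous ones. The eGFP-H2A.Z.2 count per eGFP-H2A.Z.1 peak had a median of 0.862 over the 547 bins with at least 25 eGFP-H2A.Z.1 peaks, with 90% of bins between 0.688 and 0.966. It was highest on chromosome 22 from 25 to 30 Mb, with 100 eGFP-H2A.Z.2 and 94 eGFP-H2A.Z.1 peaks, and lowest on chromosome X from 100 to 105 Mb, with 15 and 35. Here the filter on eGFP-H2A.Z.1 peaks favours low ratios.

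Chromosome 3 was the most densely marked in every list, with 44.7 endogenous, 58.9 eGFP-H2A.Z.1 and 51.9 eGFP-H2A.Z.2 peaks per Mb. Chromosome X was the least, with 11.7, 8.31 and 5.66. The density on X was 0.377 of that of the autosomes for endogenous H2A.Z, 0.213 for eGFP-H2A.Z.1 and 0.168 for eGFP-H2A.Z.2. On X there were 1790 endogenous, 1267 eGFP-H2A.Z.1 and 863 eGFP-H2A.Z.2 peaks, so that X held 0.708 eGFP-H2A.Z.1 peaks per endogenous peak, where the autosomes ran from 0.983 on chromosome 22 to 1.35 on chromosome 8. For eGFP-H2A.Z.2 per endogenous peak X had 0.482 and the autosomes 0.876 (chromosome 19) to 1.27 (chromosome 20). The number of eGFP-H2A.Z.2 per eGFP-H2A.Z.1 peaks was 0.681 on X, below a mean of 0.866 ± 0.035 over the autosomes (SD, 22 chromosomes; range 0.79 on chromosome 4 to 0.945 on chromosome 20). Of the endogenous peaks on X, 43.5% met eGFP-H2A.Z.1 and 32.7% eGFP-H2A.Z.2. In the other direction, 61.1% of the eGFP-H2A.Z.1 and 67.6% of the eGFP-H2A.Z.2 peaks on X met an endogenous peak, above their shares of 55.2% and 58.6% over all chromosomes. The comparisons by region and chromosome were chosen after the data were examined, and none was corrected for copy number.

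**Figure D3:**
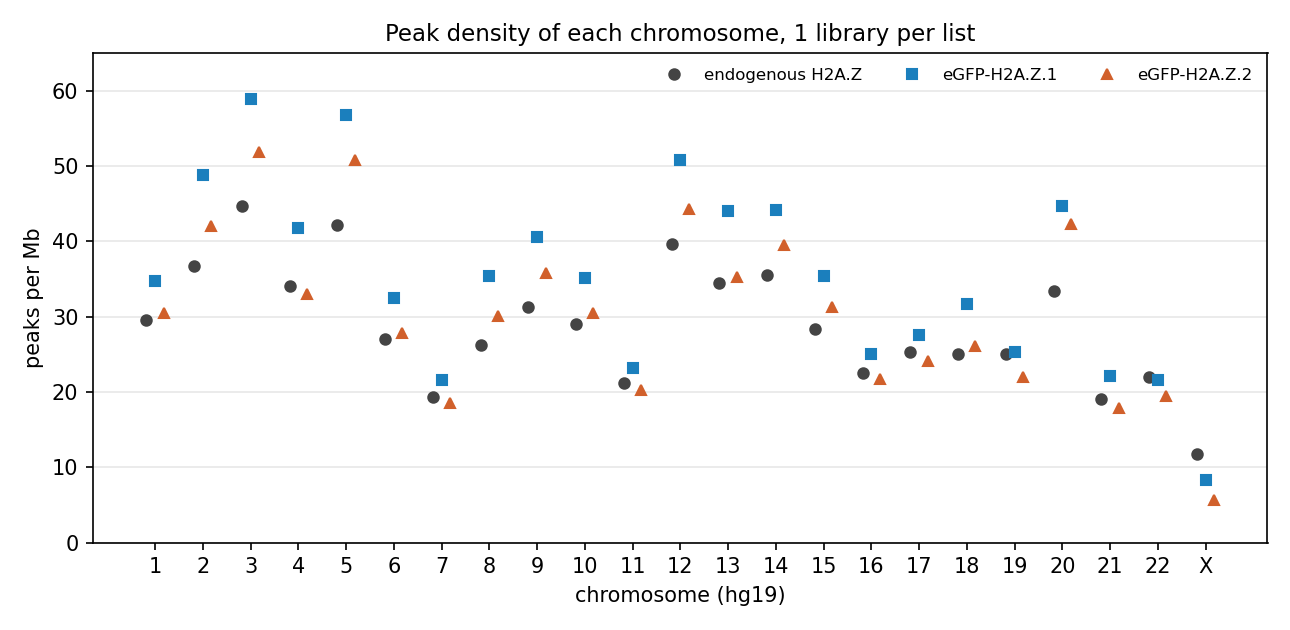
Points give the number of peaks per Mb of each chromosome for the 3 lists, 1 library each. Chromosome 3 is highest in every list, and X is lowest, with endogenous H2A.Z at 11.7, eGFP-H2A.Z.1 at 8.31 and eGFP-H2A.Z.2 at 5.66 peaks per Mb.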

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

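Shares are given in the order eGFP-H2A.Z.1 in eGFP-H2A.Z.2, the reverse, endogenous H2A.Z in eGFP-H2A.Z.1, endogenous H2A.Z in eGFP-H2A.Z.2, and the reverse of each. Merging peaks closer than 3 kb, setting the better-scored 50% of one list against the whole other list, and all alternatives for X density and peak width were chosen after seeing the data. Requiring an overlap of at least 50% of both peaks lowered all 6 shares, to 40.3%, 46.7%, 37.0%, 33.0%, 29.9% and 30.9%. Keeping the better-scored 50% of each list gave 61.6%, 70.6%, 64.5%, 59.8%, 50.9% and 54.1%. The better-scored 50% against the whole other list gave 83.4%, 90.0%, 81.3%, 76.4%, 73.3% and 76.1%. The first of these removes possible partners and the second does not. Lists of equal length gave 72.5%, 72.4%, 64.7%, 63.9%, 62.1% and 61.1%. In the full lists the directions of the isoform comparison had similar counts of overlapping peaks, 74194 and 73666. Cutting the lists to one length therefore brings their shares together by arithmetic, which is no separate result. Merging peaks closer than 3 kb gave 69.1%, 79.8%, 71.2%, 65.8%, 61.4% and 65.2%, and the planned merge at 1 kb changed nothing because no peaks lay that close. Relative to the autosomes, the density on X among the better-scored 50% was 0.327 for endogenous H2A.Z, 0.173 for eGFP-H2A.Z.1 and 0.143 for eGFP-H2A.Z.2. With equal-length lists it was 0.198 for eGFP-H2A.Z.1 and 0.169 for eGFP-H2A.Z.2. Its order over the lists held in these settings. At 3 kb the wide peaks numbered 4081 endogenous, 10522 eGFP-H2A.Z.1 and 9924 eGFP-H2A.Z.2, and at 10 kb 16, 239 and 347. As shares of each list these were 4.59%, 9.56% and 10.4% at 3 kb and 0.018%, 0.217% and 0.365% at 10 kb, so by share eGFP-H2A.Z.2 was highest at 3, 5 and 10 kb. Other promoter widths and the settings meant for gene counts were not run for want of an annotation of the build used here. With 1 library per group no replicate could be left out, and unknown depth limits any reading of differences in peak number or width.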

Other observations

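Of the tests below, those on the score of unmatched peaks, on copy number and on the number of neighbouring peaks were chosen after their results had been seen, and the patterns themselves were found in these data. The endogenous peaks of chromosome 19 scored high, with a median of 59 against 42 over all chromosomes and 22.4% of them in the best-scored 10% of the endogenous list. For eGFP-H2A.Z.1 the share was 16.3%. On X only 3.02% of endogenous peaks were in the best-scored 10%, although the best peak of the list was there. That peak, on chromosome X from 77359130 to 77360027, had 2.27 times the score of the next one and was met by neither tagged list. Its nearest eGFP-H2A.Z.1 peak was 10781 bp and its nearest eGFP-H2A.Z.2 peak 316792 bp away. What sequence lies under this peak was not determined. Reads from expression-vector sequence were not tested for. The peak was called in the unmodified line and in neither of the transduced ones, but this does not decide the question. The lists also differ in antibody or beads, and the controls of the tagged calls, which are not given in the sources used here, may have carried the same sequence. The next-best endogenous peaks without a tagged peak were on chromosome 3 from 48481141 to 48481662 (score 204) and on chromosome 16 from 48643799 to 48644623 (score 203).

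Peaks of one isoform alone may be sites occupied by both isoforms that fell just under the calling threshold in one list. The unmatched share in the best-scored 10% was at most 0.052 of that in the lowest-scored 10% in both tagged lists, but this is the observation that prompted the explanation and decides nothing, and signal under the threshold was not analysed here. Edges placed up to 1 kb apart are argued against as the main source, since only 4.39% of peaks in eGFP-H2A.Z.1 alone lay within 1 kb of an eGFP-H2A.Z.2 peak. The reverse share was 6.94%. After shifting the shares were 6.42% and 7.59% (7.05 to 8.11 over the shifts for the latter). Peaks of one list lay at least 1201 bp apart, and shifting does not keep the room this leaves around unmatched peaks. No conclusion is drawn from the shifted levels. An isoform preference at weak sites was not tested and stays open, as does a difference in depth.

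Chromosome X had fewer tagged than endogenous peaks. Matched on measured score and width, the overlap of endogenous peaks on X with either tagged list stayed below every autosome. The score comes from 1 library and may not capture peak strength fully, so the matching can be incomplete. Lower scores or narrower peaks on X are therefore not excluded as the whole source. Compared with endogenous peaks of the same score and width, the overlap with eGFP-H2A.Z.1 on X was −22.387 percentage points from the expected 65.9%. For eGFP-H2A.Z.2 it was −27.7 from the expected 60.4%. Chromosome 19, the lowest autosome, was at −8.45 and −10.97. The expected shares lay below the 70.7% and 65.4% over all endogenous peaks, so score and width went with a part of the difference. Matched also on local peak density, X was at −10.844 for eGFP-H2A.Z.1 and −15.8 for eGFP-H2A.Z.2, with chromosome 4, the lowest autosome, at −6.61 and −8.58. Low peak density thus went with a part of the difference, and whether that part came from sparse sites or from copy number was not told apart. Density was counted in the endogenous list alone, over a single window size and with coarser width classes. The matching may therefore be incomplete, and the remainder is not shown to be independent of density. With the number of neighbouring peaks itself matched, X was at −9.71 and −13.5 and chromosome 4 at −6.89 and −8.86. Copy number of X stays open because the input was not analysed here, and the low density on X in the endogenous list, 0.377 of the autosomes, does not by itself tell a lower copy number from sparse sites. A difference in the controls, in depth or in X between the lines, and a lower incorporation of tagged H2A.Z on X, were not tested.

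Some of the strongest endogenous peaks had no tagged counterpart, 331 of the 8889 in the best-scored 10% (3.72%). They were narrow, with a median of 673 bp against 1309 bp for the others, and in 3 equal groups by width 8.20% of the narrowest and 0.304% of the widest of the 8889 lacked a tagged peak. They were most frequent on X (7 of 54 peaks, 13.0%), chromosome 7 (21 of 224, 9.38%) and chromosome 11 (23 of 309, 7.44%). These numbers are small and the chromosomes were not matched on width, so no conclusion is drawn from their order. Shifted edges are argued against as the main source, since only 1.51% of the 331 peaks lay within 1 kb of a tagged peak and the median gap was 14.7 kb. After shifting the share was 7.69%, but shifting does not keep the spacing between peaks, so no conclusion is drawn from that level. Cross-reaction of the antibody, loci altered in copy number and sites refused by the tagged protein are candidate explanations that were not tested.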
